A study of Mus musculus with 36 samples.

How the data were processed

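The data are bulk RNA sequencing counts of 36 hippocampal input libraries from female mice aged 6 months. Per the labels' protocols, heterozygous APP and Tau mice were crossed with Pvalb-Cre and then with RiboTag mice, all mice were handled on 3 days, and trained mice swam 6 trials per day for 5 days with a probe test 24 hours after the last trial. Both hippocampi were homogenised, and part of the supernatant left after mitochondria were spun down was kept as the input fraction. Per the same protocols, poly(A) libraries were made from 100 ng of RNA and sequenced on an Illumina instrument in pairs of 150 bp with 40 M reads planned (M for mega). The genotype, training state and sample number were read from the labels. The labels number the samples and do not say that each came from its own mouse, so p-values measure the spread between these samples, which may in part be technical.

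The authors deposited raw counts per gene, as whole numbers, in a table of 50559 gene symbols, and no normalised values were used. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.39 and the genome build was mm39. The aligner, the counting tool and the gene annotation are not given in the sources used here. Of counts from 1 to 10, 54.7% were even, against 50% of counts over 1000, as separate counting of both mates of a pair would give, though this was not tested, and totals of 69.2 to 124.8 M per library (median 85.4) exceed the 40 M reads planned. If mates were counted apart, small counts are less precise than they look. Whether strand was used in counting is not given, so overlapping and antisense genes, and pseudogenes such as Lamr1-ps1, are uncertain. Human transgene sequence was not part of the counted genes, so mouse App and Mapt measure the mouse genes and whatever human reads align to them. No coordinates are printed. Which genes neighbour each other was taken from a gene table of GRCm38.p6, which is not the build of the counts.

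Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Of 41519 genes with a count, 25382 passed filterByExpr by group (minimum count 10, minimum total 15) and were tested after TMM scaling. All 36 libraries of the 8 groups entered the same quasi-likelihood model with a mean per group (glmQLFit with robust estimation, glmQLFTest), and p-values were adjusted by Benjamini-Hochberg within each of 15 contrasts at 0.05. The contrasts were 3 genotypes against WT in each training state, training within each of 4 genotypes, non-additivity of APP and Tau in each training state, and the interaction of each transgenic genotype with training. CPM values are the deposited counts divided by each library's TMM-scaled total in M, and means carry the SD between libraries.

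41 gene lists were fixed, covering immune, neuronal, metabolic and stress pathways, cell types, and tissue that borders the hippocampus. Each was tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, and again with an estimated correlation. With the preset correlation 247 of the tests of 41 lists in 15 contrasts passed, and with an estimated correlation 0 passed after adjustment. The p with an estimated correlation therefore stands beside most list calls. Several lists share members, and most members are also expressed by other hippocampal cells. A list score is the mean log2 CPM of its members in a library minus the mean over all libraries.

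The rule for named genes took App, Mapt and Prnp in each genotype comparison and Pvalb and Rpl22 once. In each of the 10 genotype and training contrasts it took the 8 highest and 8 lowest log2 changes among genes past the threshold with a mean log2 CPM of at least 0 and a symbol that is not a predicted name, and up to 4 members of each list that passed over all genes. In the 5 other contrasts it took the 5 smallest p-values that passed, where none passed the 3 smallest as values, and the member with the smallest p of each called list. The rule as written sets no symbol or level condition where none passed, but the same conditions were applied there too, so genes with a smaller p that are predicted or under a mean log2 CPM of 0 were passed over. The smallest adjusted p of each such contrast stands beside the named genes where it differs from theirs. Genes outside this rule are marked as named after their values were seen. The value of 1 gene is not reported here. The groups, contrasts, tests, lists, naming rule and the first set of other settings were chosen before the data were examined.

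These other settings were RLE size factors, no filter on low counts, the replicate number as a block, the library number of the labels as a covariate, DESeq2 1.42.0, limma-voom with quality weights, a fit on only the groups compared, WT libraries split between comparisons, an estimated correlation in the list tests, and leaving out each library in turn. DESeq2 gave no p to 4 genes in each contrast. With these and its filter on mean counts, 24112 of 25382 genes had no adjusted p for non-additivity in trained mice. The number was 7877 for APP/Tau and 3941 for Tau against WT in trained mice, 3449 for non-additivity in naive mice and 2957 for training in Tau mice. In each other contrast the filter removed no further gene. After the data were seen, leaving out both doubted libraries (the library labelled Tau trained replicate 4 and APP trained replicate 1) and a choroid plexus covariate were added, as were runs of the list tests under these and the count settings. Agreement between comparisons that share WT libraries was set beside 100 simulations of unchanged groups. For each contrast up to 100 other splits of its libraries were fitted. Score tests are two-sided permutation tests, computed in R, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

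The test was checked on counts simulated from the real means and library sizes with 67, 67 and 66 genes changed 1.5-, 2- and 4-fold. For APP against WT, naive (25369 genes), it recovered 50.7%, 64.2% and 89.4% of them in turn, with 6.2% of its calls false. For APP/Tau against WT, trained (25364 genes), it recovered 37.3%, 53.7% and 77.3%, with 8.9% false. For training in WT (25361 genes), it recovered 41.8%, 65.7% and 84.8%, with 9.2% false, so false calls ran slightly above the nominal level. At a mean log2 CPM of at least 0 the recovery of 2-fold changes was 97.4%, 84.6% and 94.9%, and below 0 it was 17.9%, 10.7% and 25%. A first version gave the fold sizes to genes of unequal abundance, which hid the rise of recovery with fold size. After that result was seen, a version with near-equal abundance per fold size and the same random seed replaced it and gave these values.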

Results

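Messenger RNA was measured by bulk sequencing in 36 hippocampal libraries from female mice aged 6 months, to ask how amyloid and tau transgenes, alone and together, alter the hippocampal transcriptome before and after spatial learning. The mice were wild type (WT, 11 libraries), carried a human APP transgene with the Swedish and Indiana mutations (APP, 8), carried a human mutant MAPT transgene (Tau, 8), or carried both transgenes (APP/Tau, 9). Naive mice stayed in the home cage. Trained mice learned to find a hidden platform in the Morris water maze, and their tissue was taken 2 hours after a probe test. All mice came from a cross in which Pvalb-driven Cre tags the ribosomal protein Rpl22 in parvalbumin interneurons, but the libraries hold the input fraction, which is RNA of the cleared tissue lysate, taken with no selection for tagged ribosomes and so not limited to these interneurons.

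The naive groups held 6 WT, 5 APP, 4 Tau and 6 APP/Tau libraries, with 79.1 to 105.6, 70.9 to 102.1, 80.1 to 88.8 and 75.4 to 115 M counts (M for mega) each. The trained groups held 5 WT, 3 APP, 4 Tau and 3 APP/Tau libraries, with 74.5 to 97.7, 77 to 124.8, 69.2 to 110.2 and 74.2 to 82.7 M counts. None of the 68 pairs of libraries from the same group was identical, and each pair differed by more than sampling noise, with a chi-square of 14.4 to 157 per degree of freedom.

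Prnp, which encodes the prion protein and lends its promoter to the tau transgene, stood at 799 ± 52.2 CPM (SD, n = 6) in WT naive and at 787 ± 39.5 (n = 5) in WT trained libraries. Across the 19 libraries not labelled Tau, Prnp lay between 728 and 879 CPM, and in 16 of the 17 Tau-labelled libraries it lay between 1423 and 2142. The library labelled Tau trained replicate 4 was the exception, with 846 CPM. Summed counts of Lamr1-ps1, Gm32754 and 4930590L14Rik, transcripts chosen as marks after their values were seen, gave the same division, with 174 to 426 counts in the 16 libraries, 0 to 2 in those not labelled Tau, and 0 in the library labelled Tau trained replicate 4. It was kept under its label, so every direction drawn from the trained Tau group includes it. Mouse App and Mapt did not follow the labels. App stood at 1398 to 1837 CPM in APP-labelled and at 1481 to 1902 CPM in other libraries, Mapt at 506 to 577 CPM in Tau-labelled and at 510 to 595 CPM in other libraries, and none of the genotype comparisons called either gene, so they do not check the labels. Usp16, which encodes a histone H2A deubiquitinase, divided the APP labels without exception, at 12.9 to 14.9 CPM in the 17 APP-labelled and 24.8 to 30.3 CPM in the other 19 libraries. Rpl22 stood at 65.8 to 84.5 CPM and Pvalb at 2.59 to 20.7 CPM over the 36 libraries.

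**Figure D1:**
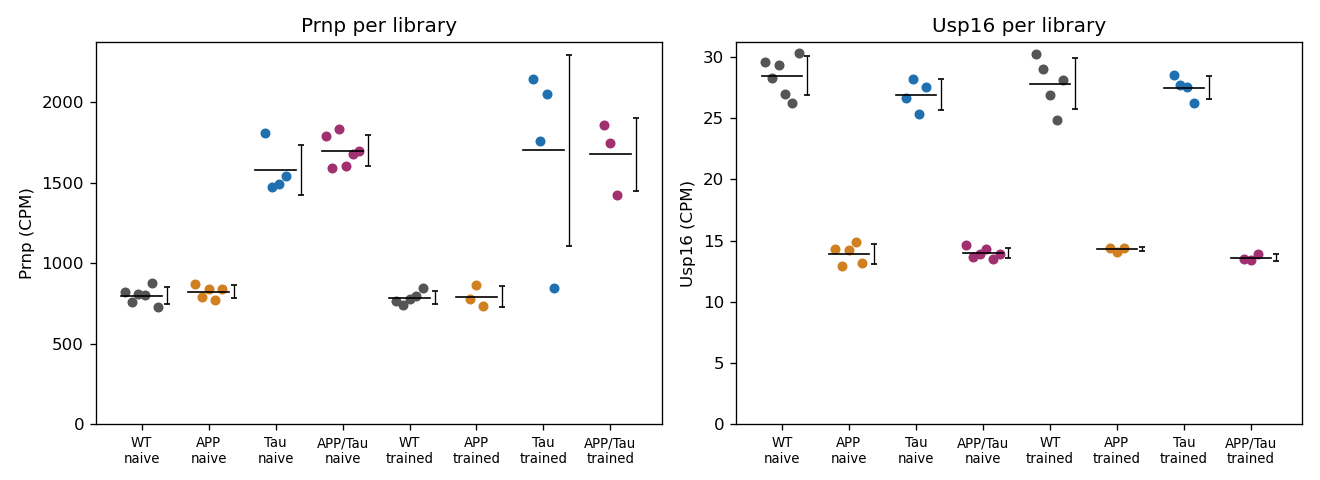
CPM of Prnp (left) and Usp16 (right) in each library, by genotype and training. Points are libraries, horizontal lines are group means and bars are the SD. Prnp stands at 1423 CPM or more in Tau-labelled libraries except the library labelled Tau trained replicate 4, at 846 CPM, and Usp16 stands at 14.9 CPM or less in the APP-labelled ones.

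In naive APP mice the hippocampal transcriptome differed from WT in 9 genes, all lower and all neighbours on chromosome 16. Usp16 fell by 1.03 on the log2 scale, from 28.4 ± 1.6 CPM (SD, n = 6) to 13.9 ± 0.825 (n = 5). Cct8, a subunit of the TRiC chaperonin, fell by 0.95, N6amt1, a methyltransferase subunit, by 1.05, Ltn1, the ubiquitin ligase of ribosome quality control, by 1.03, and Bach1, a haem-sensing transcriptional repressor, by 0.96. Rwdd2b fell by 0.91 and Grik1, which encodes a kainate receptor subunit, by 0.95. The long noncoding genes B130034C11Rik and 2810407A14Rik, named after their values were seen, fell by 1.01 and 0.92 and lie between N6amt1 and Grik1 in the gene order of GRCm38.p6. edgeR's quasi-likelihood test gave adjusted p-values from 7.62e-16 (Usp16, standard error 0.0509) to 0.0219 (B130034C11Rik) for these genes, and 933 genes had an unadjusted p under 0.05.

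Among the fixed lists, the naive APP comparison gave small shifts. In this and each other comparison, no list passed after adjustment with an estimated correlation. Cytosolic ribosomal protein genes lay slightly higher, with 76 of 78 members above 0 and a median log2 change of 0.080 (camera adjusted p = 1.28e-09, p = 0.246 with an estimated correlation). Cholesterol biosynthesis genes had a median of 0.082 (adjusted p = 7.27e-06, p = 0.098 with an estimated correlation), and no member of either list passed on its own, where edgeR called 9 genes in all, while 1 cholesterol gene passed over the list alone without WT naive replicate 3 or APP naive replicate 2. Of 25 neuropeptide and secretory granule genes, 1 fell when adjusted over the list alone, the granule protein gene Vgf at −0.36, with a list median of −0.17 (adjusted p = 0.00157, p = 0.13 with an estimated correlation). Vgf did not pass without WT naive replicate 4 or APP naive replicate 4 or 5, 2 members passed without WT naive replicate 2 or 6, and the list was no longer called without WT naive replicate 5, though its median there was −0.15. Its median was −0.089 without WT naive replicate 3 and −0.091 without APP naive replicate 4. Without WT naive replicate 5 the medians of ribosomal, cholesterol and choroid plexus genes were 0.13, 0.12 and 1.97, and the first was 0.026 with a choroid plexus covariate. Choroid plexus markers, which report tissue of the ventricle carried with the dissection, had a median of 1.18 (adjusted p = 8.36e-19, p = 0.0306 with an estimated correlation, adjusted p = 0.929). They differed as widely within groups, from a score of −2.48 upwards in WT naive libraries.

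**Figure D2:**
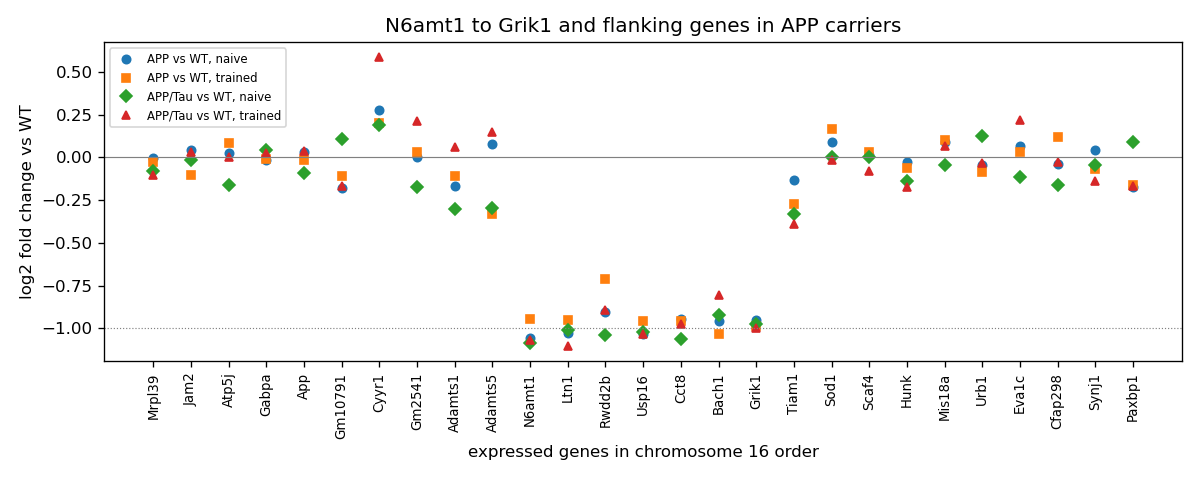
Log2 fold change against WT of the expressed genes from N6amt1 to Grik1 and of their neighbours, in chromosome 16 order, for the 4 comparisons of APP carriers with WT. Each point is 1 gene in 1 comparison. The 7 genes from N6amt1 to Grik1 average between −1.04 and −0.89, and the 20 flanking genes, App among them, average between −0.28 and 0.31.

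Trained APP mice showed the same 7 protein-coding genes lower than trained WT mice and no other call. Usp16 fell by 0.96, from 27.8 ± 2.06 CPM (SD, n = 5) to 14.3 ± 0.207 (n = 3), with a standard error of 0.062 and an adjusted p of 2.63e-12 in edgeR's quasi-likelihood test. Bach1 fell by 1.03 and Rwdd2b by 0.71, and Rwdd2b and Grik1 lost their calls on only the groups compared. Genes of cholesterol biosynthesis lay higher, with 4 of 25 members rising when adjusted over the list alone. These were Stard4, a sterol transporter, at 0.51, and the pathway enzymes Msmo1 at 0.31, Ebp at 0.30 and Sqle at 0.29, of which the last 3 were named after their values were seen. The list median was 0.12 (camera adjusted p = 7.59e-07, p = 0.079 with an estimated correlation), and no member passed without WT trained replicate 1, 2 or 5 or APP trained replicate 2, or with a choroid plexus covariate, though the list was called in each of these fits. Immediate early and activity-regulated genes had a median of 0.16 (adjusted p = 3.37e-06, p = 0.0883 with an estimated correlation), nuclear-encoded oxidative phosphorylation genes 0.15 (adjusted p = 9.22e-14, p = 0.157) and endothelial markers 0.27 (adjusted p = 4.7e-08, p = 0.0469), each with no member passing over the list alone. Choroid plexus markers had a median of 1.99 (p = 0.161 with an estimated correlation) and striatal markers, which report tissue beside the hippocampus, −0.88 (p = 0.297 with an estimated correlation). An unadjusted p under 0.05 was found for 1482 genes. Without WT trained replicate 5, whose endothelial score was −1.02 against −0.21 to 0.09 in the other WT trained libraries, the endothelial median was 0.12. Without APP trained replicate 2 the medians of cholesterol, activity-regulated and choroid plexus genes were 0.070, 0.095 and 1.21, and that of cholesterol genes was 0.20 without APP trained replicate 3 or WT trained replicate 4. Without APP trained replicate 2 the count of called genes was 11 and the oxidative phosphorylation list turned to a called decrease, whereas 36 of its members rose over the list alone without APP trained replicate 1, 48 without APP trained replicate 3 and 29 without both doubted libraries. Over the list alone 20 choroid plexus markers rose without APP trained replicate 1 and 19 without both doubted libraries, and 1 endothelial marker without WT trained replicate 4. The striatal list was no longer called without APP trained replicate 1 or both doubted libraries, with medians of −0.78 and −0.79, or without WT trained replicate 4, where its median lay above 0, while 8, 8, 8 and 3 of its members fell without WT trained replicates 1, 2, 3 and 5, 2 without APP trained replicate 3 and 3 with a choroid plexus covariate.

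Naive Tau mice differed from naive WT mice in 7 genes, all higher. Prnp rose by 0.98 on the log2 scale (standard error 0.131, adjusted p = 0.000402 in edgeR's quasi-likelihood test), to 1579 ± 157 CPM (SD, n = 4). Of the other 6, named after their values were seen, Lamr1-ps1, Gm32754, Gm32875, Gm6214 and 4930590L14Rik had almost no counts in WT naive libraries. The predicted gene Gm5802 stood at 5.85 ± 3.14 CPM (SD, n = 4) against 1.4 ± 0.177 (n = 6), spread from 1.22 to 8.14 CPM over the Tau naive libraries, and was called in no other genotype comparison. Lamr1-ps1 stood at 2.19 ± 0.584 CPM in Tau naive and at 0 in all WT naive libraries, so no fold is given. Lamr1-ps1 neighbours Prn and Prnp in the order of GRCm38.p6, and Gm6214, Gm32754, Gm32875 and 4930590L14Rik neighbour each other on chromosome 3. The count was 3 without Tau naive replicate 3, and 2363 genes had an unadjusted p under 0.05.

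Activity-regulated genes lay lower in naive Tau mice than in naive WT mice, with 35 of 38 members at or below 0 and a median of −0.23 (camera adjusted p = 3.12e-08, p = 0.0428 with an estimated correlation, adjusted p = 0.406). Over the list alone 3 fell, the neurotrophin Bdnf at −0.37, the MAP kinase phosphatase Dusp4 at −0.41 and the AP-1 subunit Fosl2 at −0.43. The number was 6, 1, 9 and 7 without Tau naive replicates 1 and 3 and WT naive replicates 5 and 6 in turn, and 5 with no filter on low counts, with medians of −0.30 to −0.23 and the list called in each. CA1 pyramidal and dentate granule cell markers lay lower too (medians −0.20 and −0.16). Several glial and immune lists lay higher with no member passing over all genes or the list alone. Interferon-stimulated genes had a median of 0.55 (p = 0.217 with an estimated correlation), disease-associated microglia genes 0.37 (p = 0.356), and myelin and mature oligodendrocyte genes 0.22 (p = 0.217). Tau naive replicate 2 alone carried the group's high microglia score, at 1.36 against −0.25 to −0.12 in the other 3. Without it neither the microglia nor the interferon list was called. Without Tau naive replicate 3, 7 interferon genes rose over the list alone. The myelin list was no longer called with a choroid plexus covariate, nor the blood list without Tau naive replicate 1 (median −0.37). The median of activity-regulated genes was −0.14 without WT naive replicate 1, of myelin genes 0.34 without Tau naive replicate 3, of choroid plexus markers 1.81 without WT naive replicate 5, and of blood markers −0.28 without WT naive replicate 2 and −0.86 without Tau naive replicate 4. Medians were 1.18 (p = 0.0751 with an estimated correlation) for choroid plexus and −0.57 (p = 0.11) for blood markers.

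In naive APP/Tau mice both sets of line-linked genes appeared together, with the same 9 chromosome 16 genes lower and Prnp higher by 1.09 (standard error 0.12, adjusted p = 8.14e-07 in edgeR's quasi-likelihood test). Npy, which encodes neuropeptide Y, fell by 0.55, from 29.1 ± 4.3 CPM (SD, n = 6) to 19.8 ± 2.63 (n = 6), with a standard error of 0.113 and an adjusted p of 0.0367. Mmp12, a macrophage metalloelastase named after its values were seen, was called at an adjusted p of 0.0162 with 0.539 ± 0.77 CPM (n = 6) against 0.00706 ± 0.011 in WT, and its counts were 139 and 134 in replicates 1 and 6 and at most 8 in the other 4. The remaining 5 of 17 called genes were the Tau-line transcripts Lamr1-ps1, Gm32754, Gm32875, Gm6214 and 4930590L14Rik. An unadjusted p under 0.05 was found for 1899 genes. The Npy call was lost in 9 of 12 fits that each left out 1 library, and held without WT naive replicates 2 and 6 and APP/Tau naive replicate 3. It was also lost with no filter on low counts, with the library number as a covariate, without both doubted libraries, with limma-voom and on only the groups compared.

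Microglial activation genes lay higher in naive APP/Tau mice. Of 32 disease-associated microglia genes, 14 rose when adjusted over the list alone and 0 over all genes, with a median of 0.76 (camera adjusted p = 3.65e-09, p = 0.124 with an estimated correlation, adjusted p = 0.384). The chemokine gene Ccl4, the member with the smallest p, stood at 0.381 ± 0.427 CPM (SD, n = 6) against 0.0382 ± 0.022 in WT. Other members, named after their values were seen, were the integrin Itgax at 4.03, the protease inhibitor Cst7 at 3.92, the lectin receptor Clec7a at 3.86, the lysozyme gene Lyz2 at 1.52 and the receptor pair Trem2 and Tyrobp at 0.77 and 0.91. Clec7a reached 12.4 and 14.3 CPM in APP/Tau naive replicates 1 and 6 and at most 1.31 in the other 4, against 0.317 ± 0.205 (SD, n = 6) in WT naive libraries. These 2 libraries also had Pvalb at 3.28 and 2.6 CPM. Adjusted over the list alone, no gene of the 32 remained without APP/Tau naive replicate 1 (median 0.50) or replicate 6 (0.48), or without WT naive replicate 2, 3 or 6, while 1 passed without WT naive replicate 4, 7 without WT naive replicate 1, 6 with a choroid plexus covariate, and 23, 22 and 22 without APP/Tau naive replicates 3, 4 and 5. The median was 0.69 to 0.79 without each of these WT libraries and 0.77 with the covariate, and the list was called in all of these fits. Homeostatic microglia markers had a median of 0.33 (p = 0.116 with an estimated correlation), where 0 passed over the list alone, against 10 with RLE size factors and 9, 9, 10 and 11 without APP/Tau naive replicates 2 to 5. Blood markers had a median of −0.35 (p = 0.184 with an estimated correlation) and were no longer called without WT naive replicate 2 (−0.14) or APP/Tau naive replicate 5 (−0.24), with −0.55 without APP/Tau naive replicate 4.

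Neuropeptide and synaptic genes lay lower in the same mice. Of 25 neuropeptide and secretory granule genes, 6 fell when adjusted over the list alone, with a median of −0.20 (camera adjusted p = 2.77e-08, p = 0.0178 with an estimated correlation, adjusted p = 0.258). Besides Npy these were Cort at −0.68, Adcyap1 at −0.50, Vgf at −0.37, Scg2 at −0.32 and Sst at −0.31, named after their values were seen, and Cort, Npy and Sst are transmitters of hippocampal interneurons. Presynaptic vesicle genes had a median of −0.10 (adjusted p = 3.72e-07, p = 0.0189 with an estimated correlation) and glutamate receptor genes −0.083 (adjusted p = 3.84e-05, p = 0.0124), both at an adjusted p of 0.258 with an estimated correlation, where the 1 member that fell was Grik1 of the chromosome 16 group, and 2 fell over the list alone without APP/Tau naive replicate 4. All 75 nuclear-encoded oxidative phosphorylation genes lay at or below 0, with a median of −0.11 (adjusted p = 4.04e-17, p = 0.116 with an estimated correlation), which was −0.062 without WT naive replicate 5. Markers of other cells and tissue moved beside them. Dentate granule cell markers had a median of −0.16 (p = 0.0915 with an estimated correlation), interneuron markers −0.047 (p = 0.0915) and myelin genes 0.23 (p = 0.11). Choroid plexus markers had a median of 0.64 (p = 0.431 with an estimated correlation) and were not called without WT naive replicate 2, 3 or 6 or APP/Tau naive replicate 2, 5 or 6 (medians 0.17 to 0.46), or with the library number as a covariate (0.24), with 1.18 without WT naive replicate 5.

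Trained Tau mice, including the library labelled Tau trained replicate 4, differed from trained WT mice in 77 genes, 25 higher and 52 lower. Prnp rose by 1.11 (standard error 0.137, adjusted p = 8.56e-05) and its neighbour Prn by 0.46. Enpp6, a choline phosphodiesterase of newly forming oligodendrocytes, rose by 0.99, from 5.88 ± 1.06 CPM (SD, n = 5) to 11.7 ± 2.41 (n = 4). Dnttip2, a nucleolar protein, rose by 0.85 (standard error 0.13, adjusted p = 0.00267), Fancf of the Fanconi anaemia complex by 0.60, the ubiquitin ligase Fbxo32 by 0.53, the splicing regulator Rbm11 by 0.47 and the transcription factor Zfp536 by 0.45. The named decreases were Noxred1 at −1.68, Fndc8 at −1.38, Cfp, which encodes the complement regulator properdin, at −1.24, the kinase Dmpk at −1.01 and Tmem86b at −0.92, followed by Pla2g4b at −0.83, Aoc2 at −0.73 and Smpd4 at −0.71. Among the other lower genes, named after their values were seen, were Tra2a at −0.56, Nxf1 at −0.49, Mettl3 at −0.39 and Jmjd6 at −0.32.

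Adjusted p-values of these named genes in edgeR's quasi-likelihood test ran up to 0.047 (Aoc2), and 3870 genes had an unadjusted p under 0.05. The 77 calls depended on single libraries. The count was 6, 12, 43, 33 and 360 without WT trained replicates 1 to 5 in turn, 3, 18 and 6 without Tau trained replicates 1 to 3, and 32 without the library labelled Tau trained replicate 4. It was 1351 with limma-voom and 538 with DESeq2. WT trained replicate 5 held 1.76% mitochondrial counts against 3.39% to 4.98% elsewhere but was not among the doubted libraries. Among the named genes, Prnp and Dnttip2 were called in all 9 fits that each left out 1 library, though Prnp was not on only the groups compared, Prn in all but that without Tau trained replicate 1, and the others were lost in 5 to 8.

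Oligodendrocyte genes lay higher in trained Tau mice. Of 30 myelin and mature oligodendrocyte genes, 18 rose when adjusted over the list alone, with a median of 0.38 (camera adjusted p = 1.4e-09, p = 0.0924 with an estimated correlation, adjusted p = 0.626). Opalin, a myelin membrane protein, rose by 1.04, and Aspa at 0.66, Cnp at 0.52, Mag at 0.45 and Mbp at 0.38 were named after their values were seen. Of 17 oligodendrocyte precursor markers, 4 rose when adjusted over the list alone, Enpp6, Sox10 at 0.40, Pdgfra at 0.23 and Fyn (p = 0.0165 with an estimated correlation, adjusted p = 0.339). The number of myelin genes was 0 without Tau trained replicate 1, 2 without Tau trained replicate 3 and 12 without WT trained replicate 2, against 23 without the library labelled Tau trained replicate 4. The list was called without Tau trained replicates 1 and 3, at medians of 0.27 and 0.35. Striatal markers moved beside them, with 10 of 16 falling when adjusted over the list alone and a median of −0.91 (p = 0.24 with an estimated correlation). WT trained replicate 4 carried a striatal score of 2.28 against −0.5 to −0.17 in the other 4 WT trained libraries, and without it no striatal marker fell, the median was −0.040 and the list was not called. No striatal marker passed without Tau trained replicate 1 or 3 or the library labelled Tau trained replicate 4, or both doubted libraries, or with the library number as a covariate, but the median was −0.87 without these libraries with the list called, and −0.71 with the covariate. For precursor markers 1 passed without Tau trained replicate 1. Disease-associated microglia genes had a median of 0.48 (p = 0.265 with an estimated correlation) and no member past the list's own adjustment, with a median of 0.29 without Tau trained replicate 3.

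**Figure D3:**
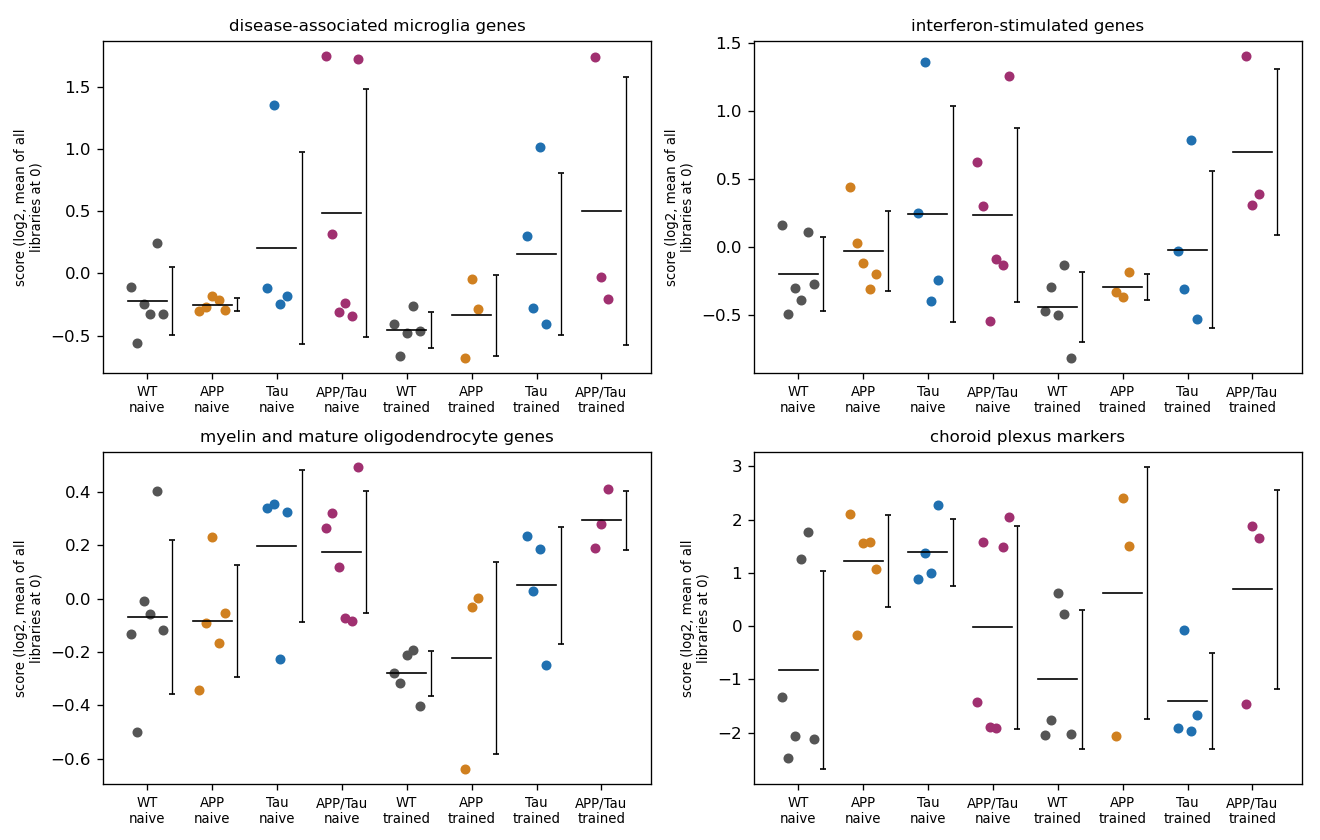
Score of 4 gene lists in each library, as the mean log2 CPM of the members minus its mean over all libraries. Points are libraries, horizontal lines are group means and bars are the SD. The microglia score reaches 1.36 in Tau naive replicate 2 and lies between −0.25 and −0.12 in the other Tau naive libraries.

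In trained APP/Tau mice 14 genes differed from trained WT mice. They were the 7 protein-coding chromosome 16 genes, all lower, and 7 higher genes, among them Prnp at 1.09 (standard error 0.147, adjusted p = 7.36e-05 in edgeR's quasi-likelihood test) and the Tau-line transcripts Lamr1-ps1, Gm32754 and 4930590L14Rik. Adamtsl4, an extracellular matrix protein, rose by 0.87 (standard error 0.168, adjusted p = 0.0227), from 6.36 ± 1.4 CPM (SD, n = 5) to 11.7 ± 1.64 (n = 3), and Aga, a lysosomal amidase, rose by 0.52 (standard error 0.105, adjusted p = 0.0373). Gstm3, a glutathione transferase named after its values were seen, was called at an adjusted p of 0.000803 from few reads, at 0.355 ± 0.375 CPM (n = 3) against 0.0492 ± 0.021 (n = 5). An unadjusted p under 0.05 was found for 2595 genes. Adamtsl4 lost its call in 5 of 8 fits that each left out 1 library, Aga in 7 of 8, and both lost it with a choroid plexus covariate and on only the groups compared, where Grik1 did too, and Aga with no filter on low counts. DESeq2 called 89 genes and limma-voom 24.

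Interferon-stimulated genes lay higher in trained APP/Tau mice. Of 32 members, 29 rose when adjusted over the list alone, with a median of 1.29 (camera adjusted p = 5.67e-26, p = 0.013 with an estimated correlation, adjusted p = 0.133). Ifi27l2a rose by 1.26, from 1.6 ± 0.196 CPM (SD, n = 5) to 3.82 ± 1.12 (n = 3), and Oasl2 at 2.62 and the transcription factor Irf7 at 2.00 were named after their values were seen. Antigen presentation genes followed, with 10 of 18 rising, such as Tap2, a peptide transporter, at 0.53, H2-K1 at 1.00 and Cd74 at 2.50 (median 0.91, p = 0.0482 with an estimated correlation). Of 19 complement genes 7 rose, among them C3 at 2.05, C4b at 1.56 and Serping1 at 1.05 (median 0.59, p = 0.0467 with an estimated correlation). Disease-associated microglia genes rose in 22 of 32 cases (median 0.96, p = 0.0792 with an estimated correlation), and lysosomal and autophagy genes in 14 of 37, such as Lamp2 at 0.43 and Ctsd at 0.72 (median 0.22, p = 0.0689 with an estimated correlation). All these counts are adjusted over the list alone, no list member passed over all genes, and beyond the first gene of each list the examples were chosen after their values were seen. APP/Tau trained replicate 1 bore much of this. Without it 3 interferon genes passed with a median of 0.76, 0 microglia genes with a median of 0.28, 0 antigen presentation genes, 0 complement genes and 1 lysosomal gene, and the complement list was no longer called (adjusted p = 0.0631). The medians of antigen presentation, complement and lysosomal genes were then 0.50, 0.20 and 0.12. This library had Clec7a at 13.8 and Pvalb at 3.15 CPM. The counts also rested on single WT trained libraries. Without WT trained replicates 1, 2, 3 and 5 in turn, antigen presentation genes gave 5, 3, 1 and 0, complement genes 2, 2, 1 and 1, and lysosomal genes 2, 2, 1 and 2. Microglia genes gave 0 without WT trained replicate 2 and 8 without WT trained replicate 3, though the medians held at 0.99 and 0.93 and the list was called in both, and complement genes 11 without APP/Tau trained replicate 3. With a choroid plexus covariate antigen presentation genes gave 4, complement genes 1 and lysosomal genes 1, with the library number as a covariate complement genes gave 2 and lysosomal genes 9, and without both doubted libraries 1 and 9. With no filter on low counts 6 lysosomal genes passed, and without WT trained replicate 4, 2 lysosomal genes fell. In these fits that kept each APP/Tau library, the medians stayed at 0.84 to 0.98 for antigen presentation, 0.53 to 0.79 for complement and 0.18 to 0.25 for lysosomal genes, and the lists were called.

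Myelin genes rose in trained APP/Tau mice as well, in 25 of 30 cases when adjusted over the list alone, with a median of 0.55 (camera adjusted p = 2.3e-24, p = 0.0102 with an estimated correlation, adjusted p = 0.133). The gap junction gene Gjb1 rose by 0.74, and Trf at 0.85, Mag at 0.63 and Mbp at 0.55 were named after their values were seen. Mbp stood at 2020 ± 65.7 CPM (SD, n = 3) against 1377 ± 223 (n = 5). Postsynaptic scaffold and kinase genes lay lower, with a median of −0.16 and 0 of 32 passing over the list alone (camera adjusted p = 1.35e-10, p = 0.0109 with an estimated correlation), and presynaptic vesicle genes had a median of −0.12 (p = 0.0392 with an estimated correlation). Without APP/Tau trained replicate 2, 12 postsynaptic genes fell over the list alone, with 3 without WT trained replicate 2, 1 without APP/Tau trained replicate 1, 4 without both doubted libraries and 1 with the library number as a covariate, while the median was −0.081 without APP/Tau trained replicate 3. CA1 pyramidal and dentate granule cell markers lay lower too (medians −0.16). Markers of other tissue and vessels moved beside them. Ependymal markers rose in 6 of 15 cases over the list alone (median 0.64, p = 0.0118 with an estimated correlation). The number was 0 without APP/Tau trained replicate 3, where the list was called (median 0.44). The median was 0.30 with a choroid plexus covariate. Choroid plexus, endothelial and blood markers had medians of 1.85, 0.38 and 0.58 (p = 0.201, 0.0253 and 0.197 with an estimated correlation). Blood markers were no longer called without WT trained replicate 1 or 5 or APP/Tau trained replicate 3 (medians 0.54, 0.53 and 0.39). The endothelial median was 0.25 without WT trained replicate 5. Myelin genes gave 15 without APP/Tau trained replicate 3 (median 0.48) and 17 with a choroid plexus covariate (0.44).

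Training changed no gene past the threshold in WT mice. Chst3, a chondroitin sulfotransferase of the extracellular matrix, had a log2 change of −0.60, Pdzd2 0.45 and Mob3b −0.60, with adjusted p-values of 0.713, 0.713 and 0.809 in edgeR's quasi-likelihood test, where the smallest of all genes was 0.122, for the predicted gene Gm15772. Striatal markers lay higher, with 3 of 16 rising when adjusted over the list alone, Adora2a, Rgs9 and Gpr6 at 1.13 (median 0.71, p = 0.327 with an estimated correlation), and WT trained replicate 4 is the library with the striatal score of 2.28. Without it the list turned to a called decrease with no member rising. The list was no longer called without WT naive replicate 1 or 2, at medians of 0.65 and 0.68. The number of members was 9, 11, 11 and 8 without WT trained replicates 1, 2, 3 and 5, 0, 0, 1 and 0 without WT naive replicates 1 to 4, 5 with a choroid plexus covariate, and 1 with no filter on low counts or without both doubted libraries. Mural and fibroblast markers had a median of −0.49 (camera adjusted p = 1.36e-10, p = 0.0198 with an estimated correlation, adjusted p = 0.76), and glucocorticoid-responsive genes 0.12 (p = 0.155 with an estimated correlation), or 0.070, 0.18, 0.20 and 0.054 without WT naive replicates 2, 3, 4 and 6. Against 0 genes by edgeR, 1486 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. The count was 2 without WT trained replicate 4 and 1 without WT trained replicate 3 or 5.

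In APP mice trained and naive libraries also gave 0 called genes, with 1329 at an unadjusted p under 0.05 and 0 by DESeq2 and by limma-voom. Nsun3, a mitochondrial tRNA methyltransferase, had a log2 change of −0.35, Jmjd6 0.24 and Nos1, the neuronal nitric oxide synthase, −0.51, each with an adjusted p of 0.883 in edgeR's quasi-likelihood test. Nos1 fell when adjusted over the list of 25 interneuron markers alone (p = 0.664 for the list with an estimated correlation), and did not without APP trained replicate 1 or 2. Activity-regulated genes lay above 0 in 37 of 38 cases, with a median of 0.18 and no member passing (camera adjusted p = 4.26e-07, p = 0.0541 with an estimated correlation). Without APP trained replicate 3, 1 gene was called.

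In Tau mice trained and naive libraries differed in markers of tissue beside and within the hippocampus. The Tau trained libraries have the library numbers 3, 4, 8 and 9 and the Tau naive ones 11, 33, 34 and 36. Training and library number therefore cannot be told apart within this contrast. Choroid plexus markers fell in 20 of 21 cases when adjusted over the list alone, with a median of −2.77 (camera adjusted p = 4.52e-13, p = 0.0678 with an estimated correlation). Ttr, the transthyretin made by choroid plexus, stood at 1803 ± 1019 CPM (SD, n = 4) in Tau naive and 168 ± 216 (n = 4) in Tau trained libraries. Ependymal markers fell in 14 of 15 cases (median −0.77, p = 0.00963 with an estimated correlation, adjusted p = 0.158) and thalamic and habenular markers in 13 of 20 (median −0.94, p = 0.0462 with an estimated correlation). Dentate granule cell markers lay higher, 13 of 20 rising and Spint2 falling, with Stxbp6 at 0.55 and, named after their values were seen, C1ql2 at 0.89, Prox1 at 0.43 and C1ql3 at 0.42 (median 0.41, p = 0.0155 with an estimated correlation, adjusted p = 0.158). Of 32 postsynaptic scaffold and kinase genes 9 rose, among them the scaffold Dlg3 at 0.26 and the kinase Camk2b at 0.28 (median 0.17, p = 0.0105 with an estimated correlation, adjusted p = 0.158). All these counts are adjusted over the list alone.

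Single genes did not pass in trained against naive Tau mice. Cfap52 had a log2 change of −1.36, Intu −0.42 and Sult2b1 0.90, each with an adjusted p of 0.0579. edgeR's quasi-likelihood test called 0 genes where 3707 had an unadjusted p under 0.05, DESeq2 called 364 and limma-voom 833, and edgeR on the Tau libraries alone called 290. The count was 192 without Tau naive replicate 1 and 1 without Tau naive replicate 2. With a library number covariate the list counts dropped to 0 choroid plexus, 1 ependymal, 0 thalamic, 2 dentate and 0 postsynaptic genes, and the medians of the first 3 to −1.01, −0.37 and −0.60. No choroid plexus marker passed without Tau naive replicate 4, Tau trained replicate 1 or 3 or the library labelled Tau trained replicate 4, though the median stayed between −2.69 and −2.58 with the list called in all 4 fits. No ependymal marker passed without Tau naive replicate 4 and no postsynaptic gene without Tau naive replicate 2, with 2 without Tau trained replicate 2. No thalamic marker passed without any 1 of the 4 Tau trained libraries or without Tau naive replicate 1 or 2, and 2 passed without Tau naive replicate 4, while the list was called in each of these fits. Dentate markers gave 4 without Tau naive replicate 3, 6 without Tau trained replicate 2 and 7 without the library labelled Tau trained replicate 4, and postsynaptic genes gave 15 without Tau naive replicate 3. Spint2 did not pass without the library labelled Tau trained replicate 4 or Tau naive replicate 3 or 4. Without both doubted libraries 0 thalamic and 8 dentate markers passed, and with a choroid plexus covariate 0 choroid plexus, 0 ependymal and 0 thalamic markers and 1 postsynaptic gene. The ependymal median was −0.58 without Tau naive replicate 4 and −0.32 with this covariate, where the thalamic median was −0.67. Over all fits that each left out 1 library, the medians stayed at −1.17 to −0.86 for thalamic markers and 0.32 to 0.46 for dentate markers. They stayed at 0.15 to 0.20 for postsynaptic genes, and these lists were called.

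In APP/Tau mice training called 0 genes in edgeR's quasi-likelihood test, with 780 at an unadjusted p under 0.05 and 0 by DESeq2 and by limma-voom. Sncg had a log2 change of 0.90, the neurofilament gene Nefm 0.30 and Gapdh-ps15 0.68, each with an adjusted p of 1, where the smallest of all genes was 0.262, for Gstm3. Interferon-stimulated genes lay above 0 in all 32 cases, with a median of 0.42 and no member passing (camera adjusted p = 3.74e-08, p = 0.147 with an estimated correlation), and the list was not called without APP/Tau trained replicate 1 (median 0.011), with 0.71 without APP/Tau naive replicate 6. The count was 1 without APP/Tau trained replicate 1 or 2.

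Whether the double transgenic differs from the sum of both single transgenic effects was tested as non-additivity. In trained mice 3 genes passed, all below additivity. Dnttip2 had a difference of −1.62 (standard error 0.209, adjusted p = 0.000139 in edgeR's quasi-likelihood test), with 12.4 ± 1.49 CPM (SD, n = 5) in WT, 18.4 ± 5.13 (n = 3) in APP, 22.3 ± 1.71 (n = 4) in Tau and 10.8 ± 0.881 (n = 3) in APP/Tau libraries. Fmn2, an actin nucleator, had −0.82 (standard error 0.144, adjusted p = 0.0301), and Phf20, a chromatin reader, −0.72 (standard error 0.13, adjusted p = 0.0319). Phf20 stood at 71.7 ± 10.9, 75.4 ± 3.74, 97.5 ± 9.56 and 62.1 ± 5.74 CPM in the same order of genotypes. Dnttip2 was called in all 15 fits that each left out 1 library, while Fmn2 was lost in 10 and Phf20 in 11. DESeq2 gave these 3 no adjusted p, since its filter on mean counts removed 95% of genes in this contrast, and its unadjusted p was 1.43e-14 for Dnttip2, 7.3e-08 for Fmn2 and 6.36e-08 for Phf20. It called 10 genes among the rest, limma-voom called 1, and the Tau group includes the library labelled Tau trained replicate 4. That library held no counts of the Tau-line marks, yet by the SDs of the Tau group it too lay above the WT means of Dnttip2 and Phf20. Whether the tau transgene raised these genes is therefore open. Dnttip2 was the lone call without Tau trained replicate 2, APP trained replicate 1, 2 or 3, WT trained replicate 3 or 4, or APP/Tau trained replicate 2 or 3.

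Naive mice gave 0 non-additive genes by edgeR, with 1810 at an unadjusted p under 0.05, 4 by DESeq2 and 0 by limma-voom. Dnttip2 had −0.87 (adjusted p = 0.197), Phf20 −0.55 (adjusted p = 0.197) and Kctd20 0.25 (adjusted p = 0.349) in edgeR's quasi-likelihood test. Activity-regulated genes lay above additivity in 36 of 38 cases, with a median of 0.32 and no member passing (camera adjusted p = 1.83e-09, p = 0.0306 with an estimated correlation, adjusted p = 0.634). Over the list alone 2, 7 and 4 of them passed without WT naive replicates 5 and 6 and APP naive replicate 4. Choroid plexus markers had a median of −1.73 (p = 0.0309 with an estimated correlation). Without APP naive replicate 5, 1 gene was called.

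The interaction of genotype with training called 0 genes by edgeR for each genotype. For APP, 678 genes had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0, with Fcgbp at −0.92, Myb at 1.06 and Pts at 0.31, each at an adjusted p of 1, where the smallest of all genes was 0.0956. For Tau, 2294 genes had an unadjusted p under 0.05, DESeq2 called 15 and limma-voom 0, with Fancf at 0.86 (adjusted p = 0.113), Cfap69 at −0.86 and Rrp1b at −0.63 (adjusted p = 0.207), where the smallest was 0.0608. For APP/Tau, 1052 genes had an unadjusted p under 0.05, DESeq2 and limma-voom called 0, and Gpr182 stood at 1.36 (adjusted p = 0.904), Enpp1 at 0.86 and Mgp at 1.34 (adjusted p = 0.981), where the smallest was 0.713. In the Tau interaction, Ptgs2 at 0.68, Dusp4 at 0.47 and Bdnf at 0.45 rose when adjusted over the 38 activity-regulated genes alone, without a list call (p = 0.607 with an estimated correlation), and none of them did without the library labelled Tau trained replicate 4 or Tau naive replicate 2, or with the library number as a covariate, while the list was called without WT naive replicate 6. Interferon-stimulated genes had a median interaction of 0.75 in APP/Tau with no member passing (p = 0.108 with an estimated correlation), and 2 passed over the list alone without APP/Tau naive replicate 6, with a median of 0.30 without APP/Tau trained replicate 1. The count was 1 for APP without WT naive replicate 3, APP naive replicate 4 or APP trained replicate 2. For Tau it was 6 without Tau trained replicate 2, 3, 4 and 4 without WT naive replicates 2, 3 and 4, and 1 without Tau naive replicate 2.

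Genotype effects at the same training state share their WT libraries, so their agreement was set beside a simulation of unchanged groups. The simulation drew each gene independently. It cannot show how far a correlation strays where genes move together, so a gap from it is not evidence of a shared genotype effect. Across 14716 genes, which are not independent replicates, naive log2 changes of APP and Tau correlated at 0.623 against 0.429 simulated, of APP and APP/Tau at 0.381 against 0.476, and of Tau and APP/Tau at 0.527 against 0.45. With the WT libraries split between the comparisons the values, means over 20 ways to split them, were 0.189 (0.00919 to 0.43), −0.0479 (−0.39 to 0.285) and 0.114 (−0.227 to 0.428). In trained mice the same pairs correlated at 0.251, 0.608 and 0.305 against 0.404, 0.37 and 0.411 simulated, and at −0.00948 (−0.23 to 0.179), 0.281 (0.0117 to 0.489) and 0.0956 (−0.223 to 0.477) over 10 splits. The observed covariance exceeded the simulated value by 0.00951, −0.000401 and 0.00566 in naive and by −0.00121, 0.0144 and 0.00348 in trained mice. APP and APP/Tau shared 9 lower genes in naive and 7 in trained mice, where independent lists give 0.00355 and 0.00193. These were the chromosome 16 genes from N6amt1 to Grik1, and Tau and APP/Tau shared Prnp and Tau-line transcripts, 6 genes in naive and 4 in trained mice, where independent lists give 0.00193 and 0.00689.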

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

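All tests of explanations in this part were chosen only after the results were seen, while the rule for libraries that stand apart and the interaction tests were planned.

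The 7 genes from N6amt1 to Grik1 lay lower in APP carriers of each comparison, with a median of −0.99, while the 20 flanking genes had a median of −0.011. Variants that lower mapping gene by gene would scatter the genes, and the SD between the 7 was 0.054. As the cause of these 7 decreases, a response to APP not tied to this locus is argued against by their place, since they are consecutive expressed genes, while the 0 genes outside the block called lower in all 4 comparisons restate how the block was found. An effect of APP on other genes is not excluded. Of genes that the averaged contrast called, Tiam1 is the expressed gene next to Grik1. It lay at −0.387 to −0.134 in the 4 comparisons, without a call. Hmox1 is a known target of Bach1, a gene of the block, so neither gene stands clear of the locus. What stays open is the hypothesis that 1 copy of the block is missing or silent in the APP line, for example where the transgene inserted, which the median of −0.99 would meet and no DNA read tests.

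The library labelled Tau trained replicate 4 had Prnp at 846 CPM, within the 728 to 879 of libraries not labelled Tau and below the 1423 of the lowest other Tau-labelled library, and held 0 counts of the 3 marks. Low depth is argued against, since the lowest other Tau-labelled library would give 151 mark counts at this depth. A swap within the series would need a partner, and 0 libraries not labelled Tau held over 3 mark counts. An animal or tube without the Tau transgene under this label stays open as a candidate explanation. No biological explanation was tested, since the design gives none for this library.

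Disease-associated microglia genes lay higher in APP/Tau than in WT libraries, mostly in a few of them. A larger share of microglia in an unchanged state would raise homeostatic markers as much, yet the disease-associated score rose over the homeostatic score by 0.492 (permutation test within training state, p = 0.00683, adjusted p = 0.00911, 9 against 11 libraries). Homeostatic markers rose too, at a median of 0.35 in trained mice, or 0.053 without APP/Tau trained replicate 1. The test therefore cannot exclude a larger share of microglia beside a change in their state. Blood carried over is argued against in naive mice, where blood markers had a median of −0.348, but in trained mice it cannot be told apart because the median was 0.579 with p = 0.197 at an estimated correlation. Library order is argued against, since the list median in naive APP/Tau mice was 0.784 with the library number as a covariate. A microglial response to tau and amyloid pathology that has begun in some mice at this age may account for it and remains a hypothesis, as pathology was not measured in these files.

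Of 300 groups of values tested for a library far from its group, 28 had one, where chance gives about 15. Tau naive replicate 2 stood apart with high scores for disease-associated microglia (1.36, others −0.25 to −0.12), antigen presentation (1.36, others −0.1 to −0.02), reactive astrocyte (1.28, others −0.2 to −0.09), complement (0.87, others −0.14 to −0.02) and Alzheimer disease risk genes (0.26, others −0.05 to −0.01). Tau trained replicate 3 stood apart in antigen presentation (0.98, others −0.38 to −0.2), complement (0.2, others −0.31 to −0.23) and unfolded protein response genes (−0.22, others −0.11 to −0.09). WT trained replicate 4 stood apart in striatal markers (2.28, others −0.5 to −0.17), neuropeptide (0.64, others −0.1 to 0.1), neocortical and subicular (0.28, others −0.11 to −0.03) and presynaptic vesicle genes (0.18, others −0.02 to 0.03), and in CA1 pyramidal markers (−0.25, others 0.08 to 0.15). WT naive replicate 5 stood apart in App (1900 CPM, others 1570 to 1680), the score of App, Mapt and Prnp (−0.02, others −0.22 to −0.15), oxidative phosphorylation (0.25, others −0.09 to 0.03) and lysosomal genes (0.16, others −0.17 to −0.06).

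Tau naive replicate 3 had low thalamic and habenular (−0.31, others 0.82 to 1.03) and myelin scores (−0.23, others 0.32 to 0.35). APP/Tau naive replicate 1 had low mitochondrially encoded (−0.53, others −0.09 to 0.12) and striatal scores (−0.69, others −0.12 to 0.08). Endothelial markers were high in APP naive replicate 2 (0.39, others 0.04 to 0.07) and low in WT trained replicate 5 (−1.02, others −0.21 to 0.09). Tau trained replicate 1 stood apart in Mapt (577 CPM, others 536 to 542) and heat shock genes (−0.14, others at −0.11). The neuropeptide score of APP naive replicate 4 was −0.25 (others −0.05 to 0.03), the circadian clock score of WT naive replicate 4 was −0.16 (others 0.01 to 0.06), and the choroid plexus score of Tau trained replicate 2 was −0.08 (others −1.97 to −1.66).

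In trained mice the log2 effect of APP differed with the Tau label for Dnttip2 (−1.62), Fmn2 (−0.82) and Phf20 (−0.72). This is the test of non-additivity itself and includes the library labelled Tau trained replicate 4. Fmn2 did not pass without both doubted libraries (adjusted p = 0.0643), and 11 of 100 splits of the libraries gave as many genes.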

How the results depend on the processing

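Leaving out both doubted libraries, the choroid plexus covariate and the list runs under the count settings were tests chosen only after the data were seen. Of 326 named gene results 0 reversed and 53 passed, and 34 of these passed in each fit that left out 1 library. RLE size factors moved no count of called genes by over 1.5 times, nor did the absence of a filter, and RLE shifted the median log2 change of all genes most for non-additivity in naive mice, by −0.00966. For Tau against WT in naive mice the count moved from 7 to 4 with a choroid plexus covariate and to 2 on only the groups compared, and for APP/Tau in naive mice from 17 to 11 on only those groups. For Tau against WT in trained mice the 77 became 244 with the library number, 49 without both doubted libraries, 156 with the choroid plexus covariate, 1351 with limma-voom, 538 with DESeq2 and 230 on only the groups compared. For APP/Tau in trained mice the 14 became 24 with limma-voom, 89 with DESeq2 and 25 on only the groups compared. For training in Tau mice the 0 by edgeR became 5 with the library number, 833 with limma-voom, 364 with DESeq2 and 290 on only the groups compared. In WT mice 0 became 1 with DESeq2. Non-additivity moved in naive mice from 0 to 1 without both doubted libraries, 4 with DESeq2 and 1 on only the groups compared, and in trained mice from 3 to 1 with limma-voom, 10 with DESeq2 and 1 on only the groups compared. The interaction moved from 0 to 1 with DESeq2 for APP, and to 15 with DESeq2 and 1 on only the groups compared for Tau. List calls went from 247 to 0 with an estimated correlation, and the correlation of naive APP and APP/Tau effects from 0.381 to −0.0479 (−0.39 to 0.285 over 20 splits) with the WT libraries split, which also took that of trained APP and Tau effects from 0.251 to −0.00948 (−0.23 to 0.179 over 10). With the library number as a covariate the choroid plexus median went from 1.18 to 0.62 for APP and from 1.18 to 0.50 for Tau in naive mice and from −1.73 to −0.90 for non-additivity in naive mice, that of cholesterol genes for APP in naive mice from 0.082 to 0.054 and of glucocorticoid-responsive genes for training in WT mice from 0.12 to 0.067. The causes of these moves were not tested.

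With the replicate number as a block, 4 genes passed for Tau in naive mice, 1 for training in Tau mice and 6 for the Tau interaction, and no other count of called genes moved by over 1.5 times. Members passing over the list alone moved more. With the block, for APP/Tau in trained mice microglia genes went from 22 to 0, antigen presentation from 10 to 1, complement from 7 to 1, lysosomal from 14 to 3, endothelial from 2 to 1 and ependymal from 6 to 10, for APP/Tau in naive mice microglia genes from 14 to 4, and for Tau in trained mice striatal markers from 10 to 4. With the block the medians of the first 4 were 0.90, 0.81, 0.61 and 0.21, that of microglia genes in naive mice 0.63 and of these striatal markers −0.75, and all 6 lists were called. Activity-regulated genes for Tau in naive mice went from 3 to 12 and for non-additivity in naive mice from 0 to 8, postsynaptic genes for APP/Tau in trained mice from 0 to 1, the neuropeptide list for APP in naive mice from 1 to 2 and striatal markers for training in WT mice from 3 to 0, and the striatal lists of that contrast and of APP in trained mice were no longer called, at medians of 0.58 and −0.60. Npy, Adamtsl4 and Aga lost their calls with the block. The numbers do not pair the libraries. Over 106 pairs with the same number the deviations from the group means correlated at −0.02 on average (−0.514 to 0.456, 31 over 0.1), other pairs at 0.00484, and 6 of 36 libraries correlated best with their own number.

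Leaving out 1 library at a time gave 7 to 10 genes for APP naive, 3 to 9 for Tau naive, 14 to 20 for APP/Tau naive, 7 to 11 for APP trained, 3 to 360 for Tau trained and 11 to 16 for APP/Tau trained. It gave 0 to 2 for training in WT, 0 to 1 in APP, 0 to 192 in Tau and 0 to 1 in APP/Tau mice, 0 to 1 and 1 to 3 for non-additivity in naive and trained mice, and 0 to 1, 0 to 6 and 0 to 0 for the APP, Tau and APP/Tau interactions. The libraries that moved a count of called genes by over 1.5 times are named in the report. Among named genes these fits lost 126 calls and gained 20, DESeq2 lost 0 of those to which it gave an adjusted p and gained 29, limma-voom lost 3 and gained 26, and fits on only the groups compared lost 10 and gained 10. Depth limits low genes, as 2-fold changes under a mean log2 CPM of 0 were recovered in 10.7% to 25% of simulated cases.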

Other observations

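Contrasts averaged over groups, the score tests and the Bach1 target test in this part were chosen only after the results were seen, while the counts over other splits were planned.

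Averaged over both APP states and both training states, Tau-labelled libraries differed from the others in 212 genes, 184 higher and 28 lower, and in 99 without both doubted libraries (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Oligodendrocyte genes were prominent. Enpp6 rose by 0.61 (adjusted p = 0.00325), Mbp by 0.36 (0.0114), Gjb1 by 0.42 (0.0114), Aspa by 0.43 (0.0124), and the myelin transcription factors Sox10 by 0.33 (0.00715) and Myrf by 0.31 (0.0185). Adjusted over the list alone, 25 of 30 myelin genes rose (camera adjusted p = 1.39e-32, p = 0.00333 with an estimated correlation, adjusted p = 0.136), and 26 without both doubted libraries (adjusted p = 0.0595 with an estimated correlation). Immune genes rose as well. C3 rose by 1.39 (adjusted p = 0.00333) and the purinergic receptor P2rx7 by 0.28 (0.00671), and over the list alone 29 of 32 interferon-stimulated genes (p = 0.0251 with an estimated correlation, adjusted p = 0.24) and 23 of 32 disease-associated microglia genes (p = 0.0462, adjusted p = 0.24) rose.

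Averaged over both Tau states and both training states, APP-labelled libraries differed in 25 genes, 8 higher and 17 lower, and in 22 without both doubted libraries. Apart from the chromosome 16 block, Tiam1 fell by 0.32 (adjusted p = 6.16e-05) and Adamts1 by 0.35 (0.0313), and both are among the genes that flank this block. Higher were the haem oxygenase Hmox1 at 0.72 (adjusted p = 0.00631), Gclm of glutathione synthesis at 0.16 (0.0154) and the glutathione transferase Gstm1 at 0.22 (0.0372). Activity-regulated genes had a median of 0.17, with 9 of 38 rising over the list alone (p = 0.015 with an estimated correlation, adjusted p = 0.242), and choroid plexus markers rose over the list alone in 21 of 21 cases (p = 0.0931 with an estimated correlation). Averaged over genotypes, training called 0 genes by edgeR with 2018 at an unadjusted p under 0.05, and the other tools were not run on it. Glucocorticoid-responsive genes had a median of 0.16 with 1 of 26 rising over the list alone (p = 0.0379 with an estimated correlation, adjusted p = 0.517).

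Bach1 represses haem and antioxidant genes, and Hmox1, Gclm and Gstm1 are among its known targets, so a hypothesis is that the lower Bach1 dose in the APP line raises them apart from any effect of amyloid. Among 14 other targets, listed after these 3 were seen, 13 lay above 0 with a median of 0.093 (camera p = 4.61e-05, p = 0.0204 with an estimated correlation), while 0 passed over the list alone. The values go the way of the hypothesis but are small, and APP carriers and the block cannot be separated in this design. No choroid plexus covariate was used, although choroid plexus markers rose in the same averaged contrast, so carried tissue was not tested as a cause.

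The disease-associated microglia score was higher by 0.653 in the 17 Tau-labelled than in the other 19 libraries (permutation test of the means, p = 0.00059, adjusted p = 0.00118), while the medians of the mean log2 CPM from which the score is centred were 2.91 and 2.74, and by 0.7 without the library labelled Tau trained replicate 4 (adjusted p = 0.00108). Among Tau-labelled libraries the APP label went with a score higher by 0.308 (exact permutation test, p = 0.439), which leaves open whether APP adds to it. Clec7a was above 5 CPM in 5 libraries, at 14.3 and 12.4 in APP/Tau naive replicates 6 and 1, 13.8 in APP/Tau trained replicate 1, 8.79 in Tau naive replicate 2 and 6.55 in Tau trained replicate 3.

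Pvalb lay at 2.59 to 3.28 CPM in APP/Tau naive replicates 1 and 6, APP/Tau trained replicate 1, WT naive replicate 3 and the library labelled Tau trained replicate 4, and at 10.7 to 20.7 CPM elsewhere. The first 3 of these are the APP/Tau libraries with Clec7a at 12.4 to 14.3 CPM, so whatever lowered Pvalb stays open beside the microglia and immune values they carry, while Clec7a was 0.219 and 0.059 CPM in the other 2. Xist stood at 2.6 CPM in APP trained replicate 1 and at 109 to 471 CPM in the other 35 libraries. In the same library Eif2s3x, an X-linked gene that escapes inactivation, stood at 47.6 CPM against 72.3 to 101 elsewhere, and Kdm6a at 27.1 against 28 to 41.1. Summed counts of Y-linked genes were 0 in APP trained replicate 1, so these values do not point to a male sample. The sum was 62 in Tau trained replicate 3. The cause was not tested for either library.

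Each count of called genes was set against other splits of the same libraries. For Tau trained the real split alone reached 77 genes (1 of 100 splits as large, highest other 5). Few splits reached the real count for APP naive with 9 genes (3 of 100, highest other 51), Tau naive with 7 (2 of 100, highest other 9) and APP/Tau naive with 17 (2 of 100, highest other 88). These shares argue against chance without excluding it, since they were not adjusted over the contrasts and some other naive splits called more genes. By this count alone chance is not argued against for the 7 genes in APP trained (4 of 56, highest other 357), the 14 in APP/Tau trained (8 of 56, highest other 414) or the 3 for non-additivity in trained mice (11 of 100, highest other 412). The 7 genes in APP trained are the chromosome 16 block, called also in both naive comparisons of APP carriers. They were kept in 8 of 8 fits that each left out 1 library, though Grik1 and Rwdd2b were lost on only the groups compared. Usp16 parted the APP labels without exception. The splits therefore bear on how many genes were called and not on which. Where 0 genes were called each split is as large by construction and the count decides nothing, with 100 of 100 for training in WT (highest other 788), 56 of 56 in APP (1), 35 of 35 in Tau (1) and 84 of 84 in APP/Tau mice (429), 100 of 100 for non-additivity in naive mice (2), and 100 of 100 for the APP (344), Tau (120) and APP/Tau (3) interactions. Splits that call many genes where the real split calls few point to a structure of these samples, which was not tested further, and a few libraries that stand apart falling together in a small arm would give the same.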
